A study of Acrobeloides nanus with 194 samples.

How the data were processed

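RNA was measured in 194 samples of the nematode Acrobeloides nanus, each holding 1 hand-separated blastomere or a small cluster of cells from an embryo. Libraries were made with CEL-Seq2, a method that tags the 3' end of transcripts with a barcode per sample before the samples are pooled, per the labels' protocols. The authors deposited a table of counts, as whole numbers per row for each library, and the tools named in the submitters' processing notes are CASAVA 1.8, Bowtie2 2.1.0 and HTSeq 0.5.4p3. The settings of these tools, any filter on reads and whether duplicate reads were collapsed by molecular identifier are not given in the sources used here. The highest of all values was 1024, the number of sequences that 5 bases can form, and 22 values stood at it; no source used here states the length of an identifier. If identifiers of that length were collapsed, the most abundant transcripts are compressed near that value.

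The deposited counts cover 16853 rows with no row identifiers. The authors also deposited an annotation of 16853 transcript contigs from 28 to 16014 bases long, in which each contig is a single feature. The contig lengths and identifiers were the only other deposited values read. The files do not pair the rows with contigs or gene names, so a row is named here by its position in the count table (row 1 is the first after the header) and no gene is named. The lists of marker genes and protein families fixed before the data were examined could not be used for that reason. Columns were matched to samples by the number that ends each sample's description, and 0 columns were left unmatched.

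Samples were grouped by the stage and cell in their titles, which put 145 libraries into 68 groups, 27 of them with 2 or more libraries. The remaining 49 libraries had titles that do not say which cell they hold, and entered no comparison of rows. Where the stage label disagreed with the title the title was used, which concerned 13 libraries titled Comma or VE with the stage label gastrula and 1 titled E4 with the stage label stage E2. Totals are given by stage label, and shares of counts by the stage in the title. Medians of shares and 1 form of their test also include libraries whose titles give the stage alone, a choice made after seeing the data. The 2 libraries titled p4 at the 4-cell stage were kept apart from P3. The label c4 cell of 1 library was read as 4 cell. Libraries under a total of 10000 counts were left out of every comparison, which removed 44 and kept 150. An early embryo has 1 cell of each name, so replicates of an early cell come from different embryos. Cells of different names can share an embryo, so tests that pool the cells of a stage measure the spread between cells, not embryos. For the pieces taken at the E8, VE and Comma stages no label names the embryo, and p-values there measure the spread between pieces that can share an embryo. Totals ran from 973 to 1217040 counts per library with a median of 28629.5, and 49.5% of all values were 0, so a row at 100 CPM gives about 1 count in a library of 10000. The closest pair of replicates differed by a chi-square of 2.55 per degree of freedom over 5718 rows, more than counting noise, and no library was treated as a duplicate.

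Groups were compared with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1), with TMM normalization, filterByExpr (minimum count 10, minimum total 15) and robust dispersions; a row was called at a Benjamini-Hochberg adjusted p under 0.05. Groups of a stage shared 1 fit. The comparison of the E8 and 2-cell stages set the mean of 4 E8 group means against the mean of the AB and P1 means. Before the data were examined, the comparisons, their tests, the alternatives and the rule for named rows were fixed. The rule took from each comparison the 2 rows that rose and the 2 that fell with the smallest p, past the threshold and detected in more than 50% of the libraries of the higher group, and followed the row with the smallest p of each comparison that supplied a set. Standard errors of log2 fold changes are the values that give the test's F.

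Sets of rows from 1 comparison were tested in comparisons without a shared library, with camera at a preset correlation of 0.01 (33 tests, Benjamini-Hochberg over all). A set held the rows called in its direction, at most the 200 with the smallest p. With fewer than 10 called, the 50 rows with the smallest p in that direction were used. Detected rows, with at least 1 count, were compared by exact permutation, and the likeness of libraries by 100000 permutations of group labels. Components were computed over 904 rows with 2000 or more counts, as log2(CPM + 50), blind to the groups. The first held 24.3% of the variance and its sign was set so that deeper libraries score higher; 78 libraries scored below 0 and are called low-score libraries. That score was related to the share of counts in the rows lower at E8 (Pearson r 0.786 over 150 libraries), so shares were compared over all libraries first. Same-numbered libraries were checked for pairing by the correlation of their deviations from the group means; no comparison had every pair above 0.1 and none was treated as paired.

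Alternatives were edgeR with DESeq2 size factors, DESeq2 1.42.0, no filter on low counts, no minimum total or one of 50000, each replicate left out, the replicate number as a block, other readings of the labels, an estimated correlation and fry for the set tests, thinning to 10000 counts for detection and rank correlation for likeness. Chosen after seeing the data were fits without the low-score libraries, fits with every library thinned to 10000 counts, and, for E8 against 2-cell, fits without E8_ant_mesoderm and with each stage as 1 group. For the 3 comparisons with calls, fits without each replicate and with the replicate block were also repeated on the rows tested in the main design (no block for E8 against 2-cell), since leaving out a library changes which rows pass the filter. Numbers of calls under alternatives are given as a percent of the rows tested in the main design of the comparison, whatever number the alternative itself tested.

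The tests were tested on simulated data, drawn from the real means and totals with 200 changed rows. Rows were drawn independently, with 1 common dispersion per comparison and no component shared by libraries. The real libraries do share such a component, so recovery and false shares in the real data may differ from those below. For E8 against 2-cell, with 4875 rows tested, 70.5% of the rows changed 4-fold and 97% of those changed 16-fold were recovered, but 20.8% of the 207 calls were false. Over 20 such simulations 17.9% of calls were false, at a median of 33.5 false calls toward lower at E8 and 0 toward higher, with a median log2 fold change of unchanged rows of -0.48. Thinned to 10000 counts the false share was 5.11%. For 2-cell P1 against AB, with 1913 rows tested, 74.7% of the 4-fold and 100% of the 16-fold changes were recovered. For 3-cell P2 against AB, with 4156 rows tested, the shares were 25.8% and 99%; for 4-cell C against AB, with 830 rows tested, 3.85% and 51.1%; and for Comma anterior against posterior, with 1088 rows tested, 48.4% and 100%. Other steps used Python 3.11, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.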

Results

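Transcripts were counted in single cells and pieces of dissociated embryos of Acrobeloides nanus, a parthenogenetic free-living nematode, from the 1-cell embryo to the comma stage. In such embryos the zygote P0 divides into AB and P1. P1 gives EMS and P2, P2 gives C and P3, and the P cells are the precursors of the germline. The early samples were AB (7 libraries) and P1 (7) at the 2-cell stage, with 3 libraries of P0. At the 3-cell stage there were AB (7), EMS (5) and P2 (6), and at the 4-cell stage AB (3), C (5) and P3 (4). Later samples were cells or pieces from 5-cell to 16-cell embryos and from stages named E2, E4 and E8. Anterior, middle and posterior pieces were titled Comma (6 each), and further pieces were titled VE or LE. Rows of the count table carry no gene names and are given by number.

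Depth varied more between libraries of the same cell than between most stages. By stage label, the median total was 105893 counts at the 2-cell stage (18453 to 418251) and 100552 at the 3-cell stage (9296 to 307179). It was 26795 at the 4-cell stage (5084 to 126438), 31298 at stage E8 (11946 to 108207) and 70724.5 with the label comma stage (30911 to 215379). P1 libraries held 208289 ± 135531 counts and AB libraries of the 2-cell stage 88902 ± 79183 (SD, n = 7 each). The number of rows detected was 14327 ± 2503 in P1 and 11488 ± 3423 in AB (SD, n = 7 each). The difference of 2840 rows did not pass an exact two-sided permutation test (p = 0.103, adjusted p = 0.308). With every library thinned to 10000 counts it was 384 rows (exact permutation p = 0.186, adjusted p = 0.35). P0 libraries had 13239 ± 5438 detected rows (SD, n = 3), 1751 more than 2-cell AB (exact permutation p = 0.55, adjusted p = 0.6), and 289 more when thinned (exact permutation p = 0.6, adjusted p = 0.6). On the first principal component of all libraries, 6 of the 14 2-cell libraries, 6 of 16 3-cell libraries and 8 of 11 stage E8 libraries scored below 0. These are called low-score libraries.

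**Figure D1:**
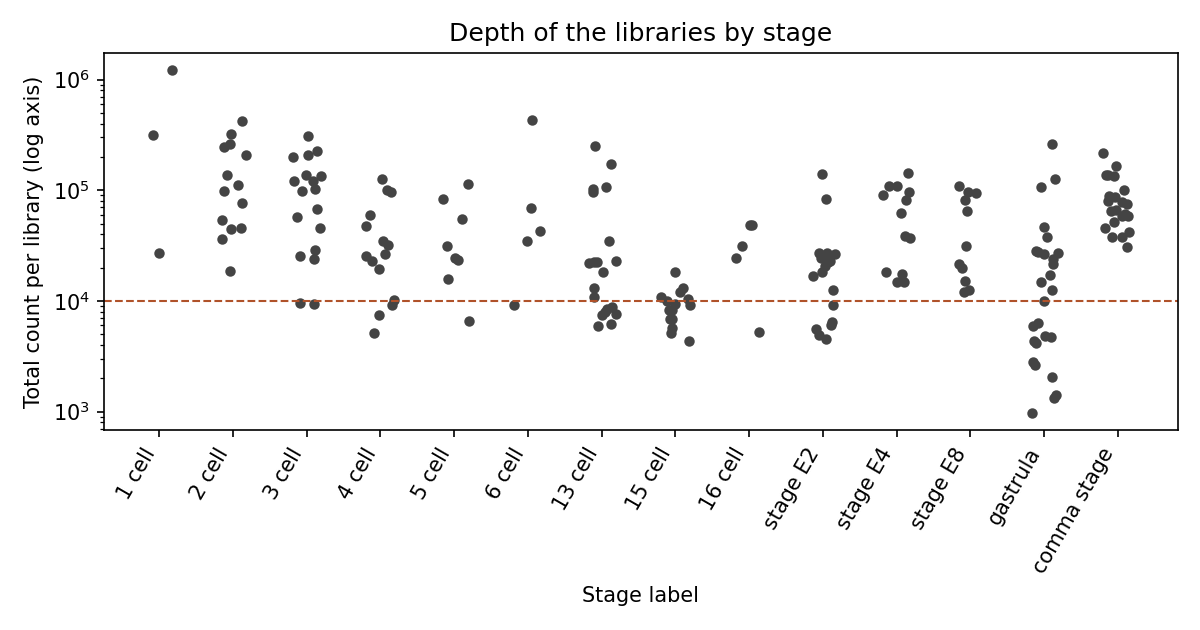
Total count of each library (log axis) by stage label, with the minimum of 10000 counts as a dashed line. Of all libraries 44 lay under the minimum, and totals ran from 973 to 1217040 counts.

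Between the 2-cell and the E8 stage, 28 rows rose and 299 fell among 4033 tested (edgeR, 14 and 10 libraries). AB and P1 libraries of the 2-cell stage can share an embryo and entered as separate, without a block. The p-values thus measure the spread between cells and pieces, not between embryos. Every E8 library has a higher sample number, the number that ends its description, than every 2-cell library. A batch that followed these numbers could not be told apart from stage, and no label names one. Row 911 rose from 85.6 ± 45.1 CPM (SD, n = 14) to 1871 ± 2248 CPM (SD, n = 10), a log2 fold change of 4.17 ± 0.65 (SE, adjusted p = 0.00268). It was above every 2-cell library in 8 of 10 E8 libraries. Row 1346 rose from 62 ± 31.7 to 1312 ± 1497 CPM (log2 fold change 3.90 ± 0.64, SE, adjusted p = 0.00296), also above every 2-cell library in 8 of 10. Row 911 stood at 79.2 ± 53.4 CPM in 3-cell AB (SD, n = 7), at 4040 ± 2740 CPM in VE ant_pharynx (SD, n = 4) and at 2545 ± 1976 CPM in Comma anterior (SD, n = 6). Whether it followed stage alone is not settled, with 1319 ± 1748 CPM in 4-cell C (SD, n = 2) and 203 CPM in the 1 library of LE_p4. The 28 rising rows together held 0.151% of counts in C replicate 3 and 0.865% in replicate a. The high C value is thus that of replicate a alone, a library of 10179 counts. Other cells before stage E8 also held row 911, with 553 ± 229 CPM in the 4-cell libraries titled p4 and 1442 ± 1863 CPM in 16-cell AB (SD, n = 2 each). Row 16571 fell from 993 ± 1040 CPM, detected in 12 of 14 libraries, to 9.20 ± 23.3 CPM, detected in 2 of 10 (log2 fold change -7.54 ± 1.31, SE, adjusted p = 0.00631). Row 2855 fell from 319 ± 290 to 8.22 ± 15.6 CPM (log2 fold change -5.78 ± 1.05, SE, adjusted p = 0.00631). Most calls were lost when 1 of the 2 E8_ant_mesoderm libraries, with totals of 11946 and 15036 counts, was left alone to stand for its group. Without its replicate 1 no row was called among 7150 and without its replicate 2 there were 3 calls among 6897. On the 4033 rows tested before, either omission left 5 calls, so the larger number of rows was not what ended most of them. Without the whole group, however, 283 rows were called, of which 95 rose. From 8.11% of the rows tested, the calls went to 4.34% without 2-cell AB replicate 3, and to 2.45% and 4.76% without E8_ant_Pharynx replicates 1 and 2. With every library thinned to 10000 counts, 8 rows rose and 40 fell among 333 tested. With libraries of at least 50000 counts, 130 rose and 24 fell. In simulations at full depth, which drew rows independently, 17.9% of calls were false, nearly all of them toward lower at E8.

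Of the 299 rows that fell, the 200 with the smallest p formed a set that was followed in libraries outside both stages. It held a median of 6.11% of counts at the 1-cell stage (3 libraries), 4.29% at the 2-cell stage (14), 4.34% at the 3-cell stage (16) and 3.08% at the 4-cell stage (12). The median was 1.22% at the 5-cell stage (7), 2.15% at the 6-cell stage (4), 0.88% at the 13-cell stage (13), 0.672% at the 15-cell stage (5) and 1.73% at the 16-cell stage (4). It was 0.618% at stage E2 (11), 1.74% at stage E4 (14) and 0.543% at stage E8 (11). In pieces titled VE it was 0.692% (8), in those titled Comma 0.644% (16) and in those titled LE 0.676% (8). The 28 rows that rose held 0.168% at the 1-cell, 0.144% at the 2-cell, 0.221% at the 3-cell and 0.275% at the 4-cell stage. They held 0.346% at the 5-cell, 0.394% at the 6-cell, 0.247% at the 13-cell, 0.636% at the 15-cell and 1.19% at the 16-cell stage. At stage E2 they held 0.417%, at stage E4 1.19% and at stage E8 0.782%, and in pieces titled VE, Comma and LE 1.44%, 0.965% and 2.07%. These medians include libraries whose titles give a stage but no cell or piece. Without those, stage E2 (4 libraries) stood at 1.62% of the falling and 0.397% of the rising set, and LE (3) at 0.579% and 0.32%. Without low-score libraries some medians were far from these. The rising set then held 1.04% at the 13-cell stage (5), 1.67% at stage E4 (10) and 2.31% at stage E8 (3), and the falling set 4.54% at the 5-cell stage (2). The order of E4 and E8 in the rising set thus depended on which libraries were kept. Other medians moved as well. The falling set then held 7.71% at the 2-cell (8) and 1.93% at the 13-cell stage (5). Stage E2 (2) stood at 1.36% of the rising and 1.42% of the falling set. The 27 libraries of named pieces titled Comma, VE or LE were set against all 28 libraries of the 3- and 4-cell stages. Their log2 share of the falling set differed by -2.06, with medians of 0.649% and 3.78% (two-sided permutation p = 1e-05, the smallest that 100000 permutations give). For the rising set it differed by 1.68, with medians of 1.04% and 0.252% (permutation p = 1e-05, the smallest possible). With all 32 libraries of those titles, named piece or not, the differences were -2.03 and 1.87 (permutation p = 1e-05 for both, the smallest possible). The 2-cell and E8 values belong to the libraries that chose the sets. Replicates 1 of E8 post_E, post_Abp, ant_Pharynx and ant_epithelia, lowest in sample number, held 1.65% to 2.64% of the rising set. The other E8 libraries held 0.363% to 0.831%. At the 4-cell stage AB replicate 2, C replicate a and the p4 libraries, among the highest in sample number, held 0.457% to 0.865%. P3 replicate a, also among the highest, held 0.281%, and the rest 0.151% to 0.329%. Libraries were permuted singly in these tests, though those of 1 stage can share an embryo. Over all 150 libraries the log2 share of the falling set rose with the score on the first component (Pearson r 0.786, permutation p = 1e-05; Spearman rho 0.762, permutation p = 1e-05; r 0.777 without the 2 libraries farthest from the median score). Both p are the smallest possible, and score and share come from the same counts.

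**Figure D2:**
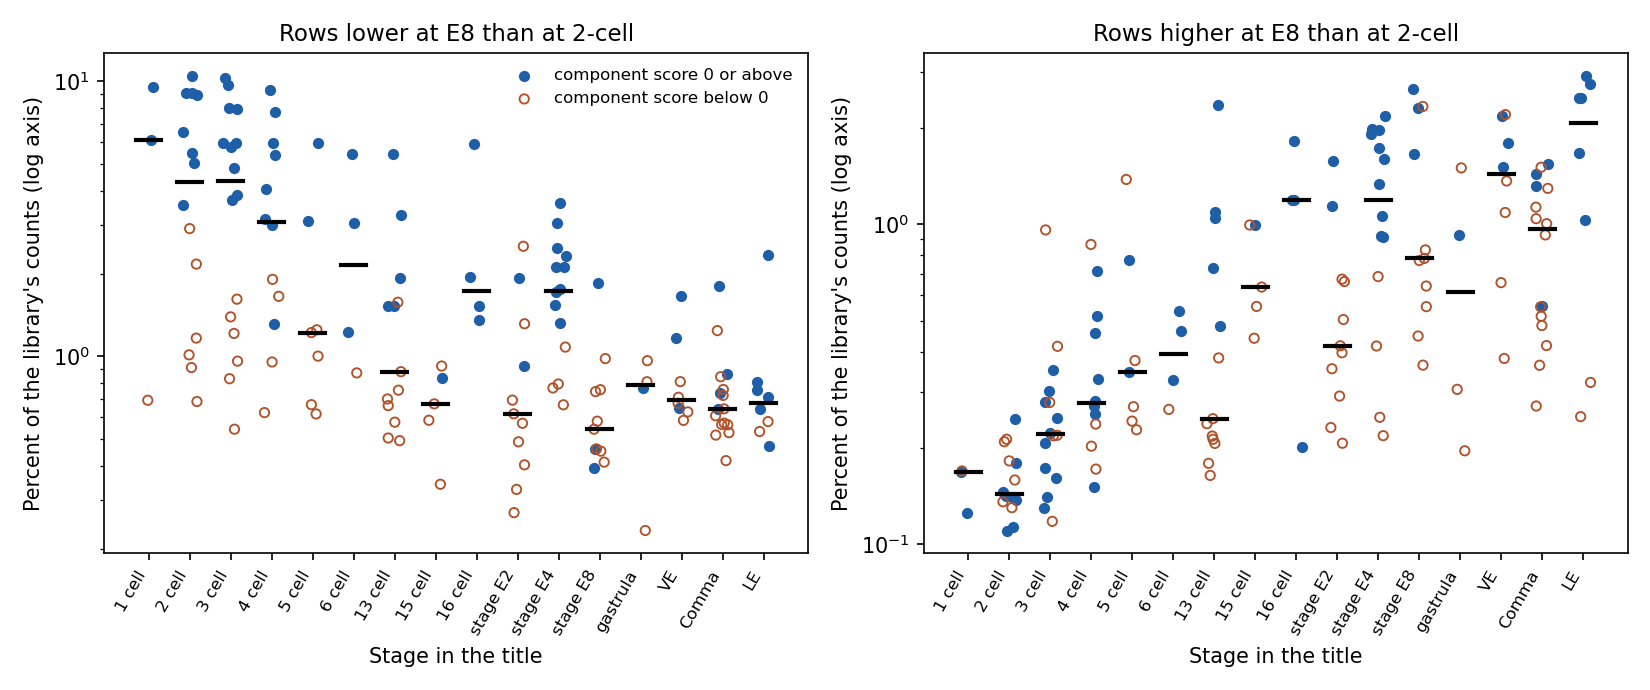
Percent of each library's counts (log axis) in the 200 rows lower at E8 (left) and the 28 rows higher at E8 (right), by the stage in the title. Filled points have a first-component score of 0 or above, open points lie below 0, and bars are medians of all libraries of a stage, named cell or not, from 4.29% at the 2-cell stage to 0.543% at stage E8 on the left.

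At the 4-cell stage the rows of this falling set leaned higher in P3 and C than in AB, past the threshold of camera at a preset correlation and of no other test run over all libraries. Between P3 (n = 4) and AB (n = 3), 77 of the 78 set members tested had a positive log2 fold change, with a median of 1.51 against 0.33 for all rows tested (camera, adjusted p = 6.31e-15; adjusted p = 0.747 with an estimated correlation). Between C (n = 2) and AB, 71 of 78 were positive, with a median of 1.07 against -0.04 for all rows (camera, adjusted p = 1.45e-10; adjusted p = 0.747 with an estimated correlation). Directional fry gave an adjusted p = 0.756 for both. Without low-score libraries camera at the preset correlation passed for both as well, with medians of 1.43 and 1.34 over more members (adjusted p = 5.53e-16 and 2.25e-16; no estimated correlation was run there). That fit kept 1 C and 2 AB libraries, chosen by a score related to this set's share. Among 682 rows tested, no row passed the threshold by itself in edgeR. C minus AB had 22 rows at an unadjusted p under 0.05 and 0 calls by DESeq2, P3 minus AB had 61 and 1, and P3 minus C had 14 and 0.

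At the 3-cell stage P2 differed from AB in 4 rows that were higher and 2 that were lower among 3097 tested (edgeR, 5 and 7 libraries). Row 2159 stood at 213 ± 122.05 CPM in P2 (SD, n = 5) and 31.4 ± 21.7 CPM in AB (SD, n = 7), a log2 fold change of 3.04 ± 0.48 (SE, adjusted p = 0.00597). In 4 of 5 P2 libraries it was above every AB library. Row 8539 stood at 208 ± 144.9 CPM in P2 and 18.6 ± 19.4 CPM in AB (log2 fold change 3.08 ± 0.53, SE, adjusted p = 0.0121). Row 10236 was detected in 1 of 5 P2 libraries and in all 7 AB libraries, at 3.91 ± 8.75 and 127.2 ± 74.6 CPM (log2 fold change -4.49 ± 0.83, SE, adjusted p = 0.0204). Row 3985 stood at 10.2 ± 17.9 CPM in P2 and 134.5 ± 75.9 CPM in AB (log2 fold change -3.22 ± 0.67, SE, adjusted p = 0.0391). At the 4-cell stage, where neither was called, row 2159 averaged 108.1 ± 79 CPM in P3 and 23.8 ± 26 CPM in AB (SD, n = 4 and 3). Row 10236 averaged 31.4 ± 25.9 CPM in P3 and 106.9 ± 30.7 CPM in AB there. The 2 libraries titled p4 at that stage, whose titles leave open whether they hold P3, had 622 ± 572 CPM of row 2159 (SD, n = 2) and no count of row 10236. DESeq2 called 32 rows higher and 82 lower in P2. Without low-score libraries, with 4 libraries each, edgeR called a number of rows equal to 4.23% of the 3097, or 2.63% of the 4981 tested there. Of these 29 were higher, and all 6 rows were among them. Leaving out P2 replicate 2, 6, 7 or 8 gave no call, but the filter then left 2, 3, 4 and 3 of the 6 rows in the test. On the same 3097 rows those omissions gave 3, 1, 4 and 1 calls. Leaving out AB replicate 1, 6 or 7 left 3 either way. Leaving out AB replicate 2, 3, 4 or 8 gave 10, 62, 14 and 19, and 11, 86, 16 and 22 on the same rows. With the replicate number as a block edgeR called none of 1547 rows (7.498% at an unadjusted p under 0.05; the block was not run by DESeq2), and on the 3097 rows it called 3, of which 1 was among the 6.

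EMS differed from AB at the 3-cell stage in 2 rows, both higher in EMS (edgeR, 4 and 7 libraries, 3097 rows). Row 560 stood at 348 ± 181.8 CPM in EMS (SD, n = 4) and 14.7 ± 13.6 CPM in AB (SD, n = 7), a log2 fold change of 4.21 ± 0.61 (SE, adjusted p = 0.00108). Row 377 stood at 181.3 ± 127.4 CPM in EMS and 6.35 ± 6.44 CPM in AB (log2 fold change 4.35 ± 0.64, SE, adjusted p = 0.00108). Every EMS library was above every AB library for both rows. Neither row was specific to EMS across stages. Row 560 averaged 263 ± 281 CPM in 2-cell AB (SD, n = 7) and 427 ± 381 CPM in VE ant_pharynx (SD, n = 4), and row 377 averaged 195 ± 227 CPM in 2-cell AB. Without low-score libraries, which leaves 2 EMS and 4 AB libraries, no row was called by edgeR (298 rows at an unadjusted p under 0.05). Leaving out EMS replicate 6 left 1 call, and leaving out EMS replicate 7 or 8 or AB replicate 2 or 4 gave 9, 6, 8 and 4. On the same 3097 rows each omission gave 2 or 3 calls, and the replicate number as a block gave none in edgeR (276 rows at an unadjusted p under 0.05; the block was not run by DESeq2). P2 and EMS differed in no row (edgeR, 389 of 3097 rows at an unadjusted p under 0.05), while DESeq2 called 18 rows higher and 3 lower in P2.

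**Figure D3:**
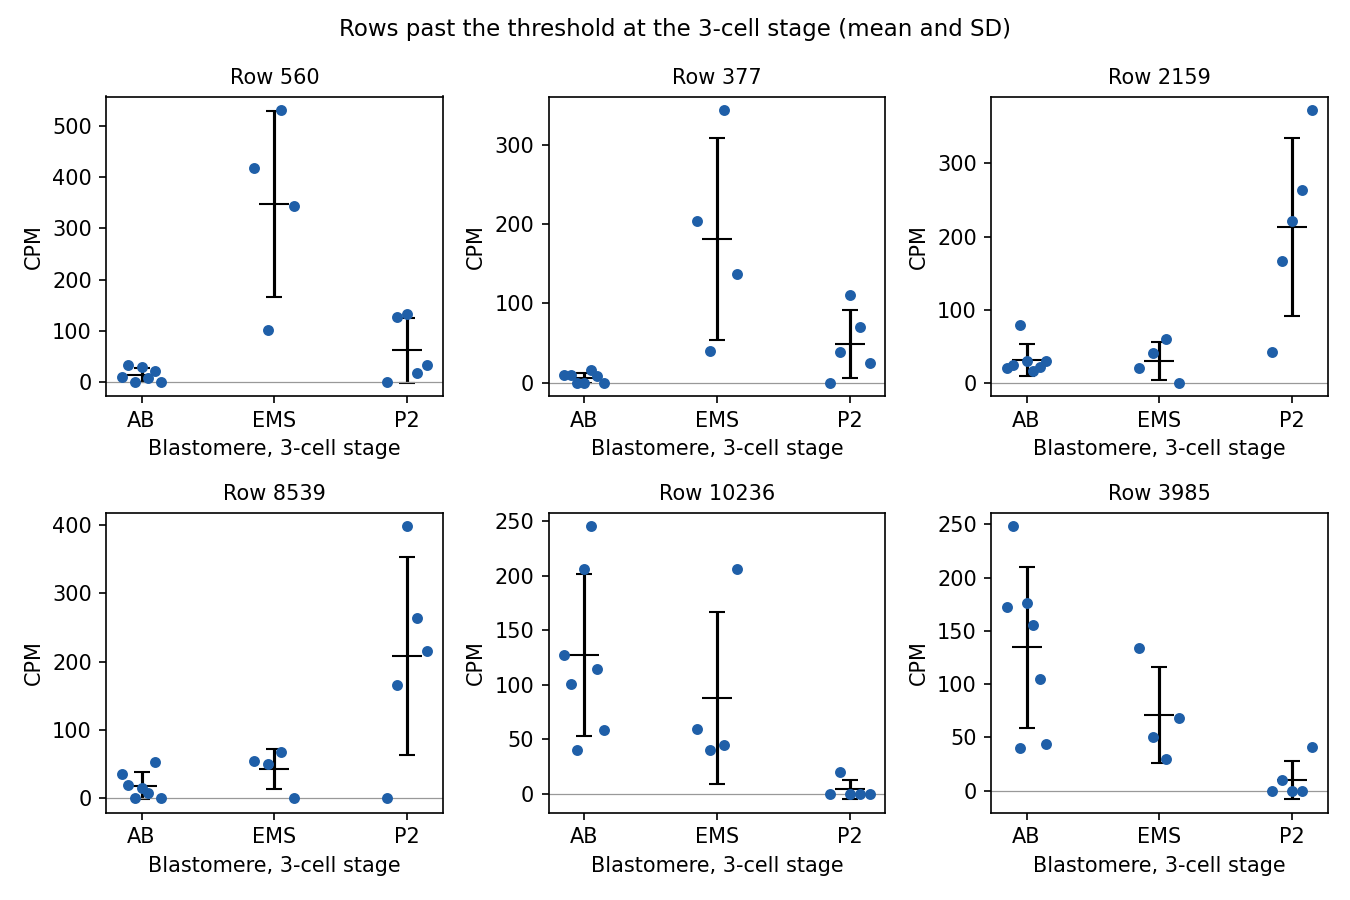
CPM of the 6 named rows in each library of AB (n = 7), EMS (n = 4) and P2 (n = 5) at the 3-cell stage; points are libraries, and bars give the mean and SD. Rows 560 and 377 are higher in EMS than in AB, rows 2159 and 8539 are higher in P2, and rows 10236 and 3985 are lower in P2.

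P1 and AB, the products of the first division, differed in few or no rows, depending on the test. At the 2-cell stage no row passed the threshold among 1536 tested (edgeR, 7 libraries each; 94 rows at an unadjusted p under 0.05; 2 lower in P1 by DESeq2). With the replicate number as a block edgeR called 2, both lower in P1. The row with the smallest p, row 7806, stood at 69.9 ± 27.6 CPM in P1 and 236 ± 145.8 CPM in AB (SD, n = 7 each; log2 fold change -1.82 ± 0.45, SE, edgeR adjusted p = 0.455). At the 3-cell stage it stood at 371 ± 322 CPM in P2 and 169.4 ± 58.7 CPM in AB. The 50 rows with the smallest p toward P1 did not pass in 3-cell P2 minus AB, with 22 of 47 members positive (median log2 fold change -0.10, -0.12 for all rows; camera, adjusted p = 0.232). In 4-cell P3 minus AB 14 of 17 were positive (median 0.66, 0.33 for all rows), also short of the threshold (camera, adjusted p = 0.384). The 50 rows toward AB were higher in EMS than in AB at the 3-cell stage, in 37 of 49 members (median 0.37, camera, adjusted p = 0.00105; adjusted p = 0.747 with an estimated correlation). In P2 minus AB they did not pass (28 of 49, median 0.37, camera, adjusted p = 0.197). Without low-score libraries they passed toward P2 and EMS, against their 2-cell direction (medians 0.59 and 0.75, camera, adjusted p = 0.0104 and 2.86e-06, no estimated correlation run there). In 4-cell P3 minus AB they leaned with their 2-cell direction, short of the threshold (11 of 27 positive, median -0.40, 0.33 for all rows, camera, adjusted p = 0.063). Without low-score libraries that median was 0.12. They were lower in P3 than in C (median -0.36, adjusted p = 0.0384; adjusted p = 0.747 with an estimated correlation; adjusted p = 0.986 without low-score libraries). The difference between the P-lineage cell and AB did not differ between the 2- and 3-cell stages in any row (edgeR interaction, 336 of 3407 rows at an unadjusted p under 0.05; not run by another tool). Fold changes were also correlated across rows, which are not independent replicates, between comparisons that share no library. Those of 3-cell P2 minus AB and 4-cell P3 minus AB had a Pearson r of 0.447 over 657 rows. For the 2-cell and 4-cell comparisons r was 0.366 over 562 rows, and for the 2-cell and 3-cell comparisons 0.127 over 1499 rows. Between 2-cell P1 minus AB and 3-cell EMS minus AB it was -0.244 over 1499 rows, with the same sign in 37.2% of them. The mean first-component score was higher in P1, P2 and P3 than in AB of their stage, and lower in EMS. Low-score libraries were 2 of 7 in P1 and 4 of 7 in 2-cell AB. At the 3-cell stage they were 1 of 5 in P2, 2 of 4 in EMS and 3 of 7 in AB. The signs of these correlations follow that imbalance. They were not computed without low-score libraries, so they cannot tell lineage from it.

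Few or no rows separated AB of the 2- and the 3-cell stage, or P1 from its daughter P2. AB of the 3-cell and of the 2-cell stage differed in no row among 1188 (edgeR, 7 libraries each, 150 rows at an unadjusted p under 0.05), while DESeq2 called 9 higher and 9 lower. Without 2-cell AB replicate 5, 1 row was called. P2 and P1 differed in no row among 2042 (edgeR, 5 and 7 libraries, 6.76% of rows at an unadjusted p under 0.05; 2 by DESeq2), and 2 rows were called without P2 replicate 6.

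Pieces of E8, VE and Comma embryos were compared to ask which rows mark a body region. Comma anterior, middle and posterior pieces differed in no row among 703 by edgeR. Anterior minus posterior had 57 rows at an unadjusted p under 0.05 and 0 called by DESeq2, middle minus posterior 74 and 9, and anterior minus middle 65 and 15, all 15 higher in the middle. Without the filter on low counts edgeR called a number of rows equal to 8.82%, 34.9% and 26.03% of the 703 in these comparisons, and without low-score libraries 7.40% in anterior minus posterior. Leaving out Comma middle replicate 4 gave 2 calls in middle minus posterior. The row with the smallest p of anterior minus middle, row 16135, had a log2 fold change of -1.99 ± 0.48 (SE, edgeR adjusted p = 0.205). VE ant_pharynx and VE middle differed in no row among 1555 (edgeR, 4 and 3 libraries, 72 at an unadjusted p under 0.05; 4 lower by DESeq2). There was 1 call without VE ant_pharynx replicate 4, and there were 5 without VE middle replicate 3. At E8 no row was called among 499 in post_Abp minus post_E (edgeR, 3 libraries each, 16 at an unadjusted p under 0.05; 0 by DESeq2) or in ant_Pharynx minus post_E (2 and 3 libraries, 32; 0 by DESeq2). Row 7373, with the smallest p in post_Abp minus post_E, had a log2 fold change of 4.43 ± 1.495 (SE, edgeR adjusted p = 0.999).

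The 50 rows leaning toward post_Abp at E8 passed a set test toward the anterior or middle in 3 of 4 comparisons of later pieces, at a preset correlation only. In Comma anterior minus posterior 25 of 28 members were positive (median log2 fold change 1.13, camera, adjusted p = 0.000107). In Comma middle minus posterior it was 21 of 28 (median 0.59, adjusted p = 0.0384), and in VE ant_pharynx minus middle 31 of 38 (median 0.80, adjusted p = 0.00211). In Comma anterior minus middle 18 of 28 were positive, short of the threshold (median 0.38, adjusted p = 0.318). The 3 that passed had an adjusted p = 0.747 with an estimated correlation. Without low-score libraries the Comma medians turned to -0.86 and -1.17 and the VE median was 0.19, none past the threshold (adjusted p = 0.178, 0.178 and 0.19). Comma anterior, Comma middle and VE ant_pharynx kept 1 library each there, so these turns carry little weight. The rows leaning toward Comma anterior or middle leaned the same way in VE ant_pharynx minus middle, short of the threshold. There 32 of 45 and 12 of 45 members were positive, with medians of 0.25 and -0.38 against 0.04 for all rows (camera, adjusted p = 0.197 and 0.144). In E8 ant_Pharynx minus post_E 16 of 21 and 20 of 30 were positive (medians 0.42 and 0.26, 0.21 for all rows; camera, adjusted p = 0.528 and 0.496). P4 and E of the 13-cell stage kept 1 library each over the minimum total and were not tested.

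Over all libraries, those of the same named cell or piece were not shown to be more alike than those of other cells of their stage (permutation test, adjusted p from 0.417 to 0.514). The mean correlations within and between groups were 0.368 and 0.379 at the 2-cell, 0.383 and 0.355 at the 3-cell and 0.398 and 0.359 at the 4-cell stage. They were 0.365 and 0.351 at E8, 0.418 and 0.398 for Comma and 0.398 and 0.411 for VE. Without low-score libraries the 3-cell stage passed, at 0.557 and 0.44 (10 libraries, permutation test, adjusted p = 0.0483).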

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

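The tests of explanations and the splits of libraries given in this part were run or read only after the results they bear on had been seen. Dixon's test on totals, detected rows, the share of the 50 most abundant rows and the named rows marked 6 of 50 groups and measures. Chance marks about 1 in 20 where values are normal, which counts near 0 are not. In P1 at the 2-cell stage replicate 2 had 9093 detected rows, far below the next lowest at 13742, and its 50 most abundant rows took 34.1% of counts against at most 15.8% in the others. P2 replicate 1 at the 3-cell stage had 41.3% of counts in its 50 most abundant rows, with the next highest at 20.5%. Row 2159 stood at 79.3 CPM in 3-cell AB replicate 4 and at most 29.4 CPM in the other AB libraries. In P2, row 10236 was at 19.6 CPM in replicate 7 and at 0 in the rest, and row 3985 was at 41.5 CPM in replicate 2 and at most 9.78 in the rest. The marks on rows 2159, 10236 and 3985 rest on a few counts each. Among the 21 libraries over the minimum total whose titles give no group, the 28 rows higher at E8 held a median of 0.928% of counts (0.207% to 2.91%).

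Rows lower at E8 than at 2-cell formed the result with the most calls, and the E8 libraries were shallower and more often low-score. Named Comma, VE or LE pieces were set against 3- or 4-cell libraries within their shared range of totals (14721 to 262472 counts, 27 and 26 libraries). That range left out few of the 28 3- and 4-cell libraries and did not match totals, so it adds little to the -2.06 over all of them. For that reason the comparison cannot decide on depth as a cause. The log2 share of the set differed by -2.071 (permutation p = 1e-05, the smallest possible). Without low-score libraries it differed by -2.469 (8 and 18 libraries, permutation p = 1e-05, the smallest possible) and among low-score libraries alone by -0.76 (19 and 10, permutation p = 0.0002), in groups set by a score that is itself related to the share. Over 58 libraries of named cells of 1-cell to 16-cell embryos outside the 2-cell stage the share fell with cell number (Spearman rho -0.369, permutation p = 0.00474, adjusted p = 0.00711 over 6 tests; Pearson r -0.333, permutation p = 0.0109; r -0.407 without the 2 libraries farthest from the median cell number), with rho -0.637 in 33 libraries that were not low-score and -0.332 in 25 low-score libraries, short of the threshold (permutation p = 0.00013 and 0.106, adjusted p = 0.00039 and 0.127). Cells of 1 embryo share its cell number and were permuted as separate libraries, so these p-values measure the spread between cells, not embryos. A decline of early transcripts over development is a candidate explanation. How many of the 299 calls depth added stays open. Simulations with 200 changed rows leaned toward false calls lower at E8, while those with no changed row gave a median of 0 calls (highest 2).

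The first component separated replicates of the same cell. Recomputed with every library at 10000 counts it had an absolute correlation of 0.9966 with the full-depth component. Unequal counting noise alone thus does not make it. Thinning cannot undo a composition that changed with depth before counting, such as compression near 1024, so depth is not excluded. Of its variance 31.14% lay between groups of 2 or more libraries, against a median of 26.4% when labels were permuted (permutation p = 0.246), so stage and cell are not its main source, though a part of it may be. AB and P1 libraries of the same number at the 2-cell stage followed each other on it (Pearson r 0.8503, exact permutation p = 0.0119). Over the 7 numbers Spearman rho was 0.893 (exact permutation p = 0.0123). Without the 2 numbers whose AB score lay farthest from the median, Pearson r was 0.881. A state of the embryo or its handling shared by both cells is a candidate explanation; the labels do not say that a number marks an embryo, and RNA degradation, arrested embryos and a shared processing day were not tested.

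Other splits of the same libraries were used to ask whether chance could give as many rows. They moved single libraries, so cells or pieces that can share an embryo were counted as separate. For E8 minus 2-cell, 1 of 100 splits, the real one, gave 327 calls, and the highest other gave 2. Without low-score libraries 1 of 100 gave 632 calls, or 8.42% of 7510 rows, with the highest other at 1.56%. For 3-cell P2 minus AB without low-score libraries, 1 of 35 splits called 2.63% of 4981 rows and the highest other 0.261%. The share is under 0.05 for these 3, the smallest that so many splits can give and unadjusted over 15 such tests, so chance can be excluded only at that level; the last 2 use libraries chosen after the data were seen. It cannot be for P2 minus AB over all libraries, where 7 of 100 splits gave 6 or more calls, up to 54 in another split. Nor can it for EMS minus AB, where 24 of 100 gave 2 or more, up to 336. Splits with several times the real count point to a structure of the samples; the excess for P2 minus AB fell to 13 calls in another split without low-score libraries, which may also be due to the smaller number of splits.

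For comparisons without a call the number of rows at an unadjusted p under 0.05 was counted. For P2 minus EMS 2 of 100 splits gave 389 or more, a share under 0.05, but the highest other split gave 536, more than the real one, and no row was called. Over 15 such tests that share does not set it apart from chance. Chance cannot be excluded for 2-cell P1 minus AB (28 of 100 gave 94 or more, up to 701), VE (19 of 35, 72 or more, up to 305) or AB 3-cell minus 2-cell (13 of 100, 150 or more, up to 356). Given as a percent of the rows tested, it cannot for 4-cell P3 minus AB (10 of 35 gave 8.94% or more, up to 17.3%) or for P2 minus P1 (23 of 100, 6.76% or more, up to 21.8%). The same holds for Comma anterior minus posterior (43 of 100, 8.11% or more, up to 19.1%), middle minus posterior (21 of 100, 10.5% or more, up to 27.5%) and anterior minus middle (31 of 100, 9.25% or more, up to 20.8%). For 2-cell P1 minus AB the highest count in another split was several times the real one, which again points to a structure of the samples. The 3 libraries each of E8 post_Abp and post_E make 10 splits, too few for a share under 0.05; the real count was 16 (6 of 10 gave as many) and the highest other 85.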

How the results depend on the processing

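Settings chosen after the data were seen are the fits without low-score libraries, those thinned to 10000 counts, those of E8 minus 2-cell without E8_ant_mesoderm or with each stage as 1 group, and those held to the rows of the main design. Calls are given as a percent of the rows tested in each comparison's main design, and where they moved the cause was not tested unless stated. E8 minus 2-cell had 8.11%. It gave 17.2% without a filter on low counts, 3.82% with a minimum total of 50000 (130 higher and 24 lower, against 28 and 299) and 15.7% without low-score libraries (285 higher and 347 lower, 205 shared with the 327). It gave 1.19% when thinned, where 333 rows were tested, which lowers the count, and 1.24% with each stage as 1 group, where 810 were tested. The 283 calls without E8_ant_mesoderm, 95 of them higher, and 312 with DESeq2 size factors were within 1.5 times. P2 minus AB at the 3-cell stage had 0.194%, and gave 3.68% with DESeq2, 0.323% without the filter, 0.0969% without a minimum total, 0.0646% with the minimum of 50000, 4.23% without low-score libraries and 0 when thinned. EMS minus AB had 0.0646%. It gave 0.161% with DESeq2, 0.807% without the filter, 0.129% without a minimum total, 0.0323% with the minimum of 50000, and 0 both without low-score libraries and when thinned.

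For results with no call by edgeR, DESeq2 gave 0.13% in 2-cell P1 minus AB, 0.678% in P2 minus EMS, 0.147% in 4-cell P3 minus AB, 1.28% in Comma middle minus posterior, 2.13% in Comma anterior minus middle, 0.257% in VE, 1.52% in AB 3-cell minus 2-cell and 0.0979% in P2 minus P1. Without the filter, P2 minus EMS gave 0.0323%, Comma anterior minus posterior 8.82%, middle minus posterior 34.9%, anterior minus middle 26.03%, VE 5.27% and AB 3-cell minus 2-cell 0.168%. A minimum of 50000 gave 0.0979% in P2 minus P1, and the stage label as a covariate gave 0.142% in Comma middle minus posterior. Without low-score libraries 4-cell P3 minus AB gave 1.91%, P3 minus C 0.733%, Comma anterior minus posterior 7.40% and VE 0.707%, from arms of 1 to 3 libraries in which a lone library is assumed to vary like the other groups. The set tests passed in 7 of 33, in 0 with an estimated correlation and 0 with fry, and in 6 of 31 without low-score libraries, where some arms hold 1 library. The excess of correlation within groups was 0.0278 at the 3-cell stage and 0.116 without low-score libraries (adjusted permutation p = 0.0483). It turned from -0.0104 to 0.0416 at the 2-cell stage without them, and from 0.0142 to -0.0163 at E8 with rank correlation, and neither turn passed the test. No named row changed direction in any setting that tested it, but each lost its call in some. Row 3985 passed in 8 of 18 settings (adjusted p up to 0.171) and row 10236 in 13 of 18 (up to 0.204). Rows 2159 and 8539 passed in all 13 and 14 that tested them, and in 12 and 10 of 13 on the rows of the main design (up to 0.0716 and 0.0809). Rows 560 and 377 passed in 16 of 18 and 14 of 16 (up to 0.0536 and 0.0675). At E8, rows 911, 1346, 16571 and 2855 passed in 32 of 33, 31 of 32, 31 of 33 and 29 of 31 (up to 0.07, 0.0723, 0.0669 and 0.0669), with log2 fold changes of 2.97 to 6.74 for row 911.

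Leaving out each replicate gave 0 to 10.7% for E8 minus 2-cell, 0 to 2.00% for P2 minus AB, 0.0323% to 0.291% for EMS minus AB, 0 to 0.284% for Comma middle minus posterior, 0 to 0.322% for VE, 0 to 0.0842% for AB 3-cell minus 2-cell and 0 to 0.0979% for P2 minus P1. Each omission also changes which rows pass the filter. On the rows of the main design the ranges were 0.124% to 11.4% for E8 minus 2-cell, 0.0323% to 2.78% for P2 minus AB and 0.0646% to 0.0969% for EMS minus AB. The samples share only a number. With the replicate block there was 0.13% in 2-cell P1 minus AB, 0.0323% in EMS minus AB, 0 in P2 minus AB, 0.2004% in E8 ant_Pharynx minus post_E and 0.0643% in VE, and no other count moved by over 1.5 times. None of the 6 rows called in P2 minus AB was among the 1547 tested with the block; on the rows of the main design the block gave 0.0969% there, with 1 of the 6 among the 3 rows called, and 0 in EMS minus AB. Same-numbered libraries correlated by 0.348 on average at the 2-cell stage (-0.053 to 0.671), where 3 of 7 pairs correlated best with their own number, and all 3 VE pairs did (0.0762 to 0.344). No value could be had for the minimum of 50000 in the 4-cell comparisons, the block in C minus AB, or the E8 regions without low-score libraries. The 13-cell P4 minus E has no residual over the minimum total; without a minimum (3 and 2 libraries, from 5952 counts) edgeR and DESeq2 called 0 of 82 rows, with 2 and 3 at an unadjusted p under 0.05. At these depths a row of a few CPM cannot be seen in most libraries.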

Other observations

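The tests in this part were chosen after the results they follow from had been seen. Cells named AB from the 3- to the 13-cell stage were compared with the other cells of their stage for their share of the 200 rows that fall by E8. Over all libraries the stage-centred log2 share differed by -0.1419 (15 AB-named and 37 other libraries, permutation within stage, p = 0.71), with medians of 1.93% and 1.57% before centring. The hypothesis that AB descendants may lose the early transcripts sooner was not borne out by that test. In libraries that were not low-score the difference was -0.6747 (11 and 17 libraries, permutation p = 0.0152, adjusted p = 0.0304 over 2 tests). That value rests on leaving out libraries by a score related to the share compared, and leaves the question open.

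The annotation's contig lengths and the rows' mean counts had a Spearman correlation of 0.001 when both were taken in the order of the files, and of 0.667 when contigs were sorted by identifier as text. No row was named from this, since an order is no identifier. The highest value in the table was 1024, found in 22 places. The table held 4 rows without a count, and these account for all 3 rows that repeat another row.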
